A study of Homo sapiens with 9 samples.

How the data were processed

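HeyA8 cells (also spelled Hey8A in the labels), an established human ovarian cancer line, were profiled on Illumina bead arrays. Per the labels' protocols, the cells were seeded on day 0, and some wells received cancer-associated fibroblasts on inserts from day 1. The medium was replaced on day 4 by medium with or without glutamine, and the cells were collected 24 h later. Total RNA was extracted with the mirVana kit and biotin-labelled cRNA was made with the Illumina TotalPrep kit, per the labels' protocols. The labels give 3 groups of 3 arrays: monoculture in complete medium, monoculture without glutamine, and coculture without glutamine. Coculture in complete medium was not analysed here. The protocol speaks of 3 wells in coculture, and the labels do not say whether the 3 samples of a group came from separate experiments or from wells of 1 experiment. The p-values therefore measure only the spread between these samples, which may be technical.

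The deposited values are on a log2-like scale, 1 value per probe and array, for 34476 probes on 9 arrays. Per the submitters' processing notes the lumi package was used. Its version and settings, the background correction and the choice between plain log2 and lumi's variance-stabilised scale are not given in the sources used here. The arrays had nearly the same quantiles, with medians from 7.4706 to 7.4731 and 75th percentiles from 7.964 to 7.9741, as after a normalization to a common distribution. Differences are therefore relative to the other probes, and a general rise or fall of RNA per cell could not be seen. Values piled up at a floor near 7.4, with an upper edge at 7.49 (the 1st percentile mirrored about the mode). Differences and folds that involve a level near this floor understate the change, and all folds assume that the scale is log2. No background intensity or detection p was used, and the number of arrays limits the precision.

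Probes were named from the platform annotation given with the values. Of the probes, 26366 had 1 gene symbol, 3 had several and 8107 had none; 26333 were found by gene identifier in the RefSeq table, and 0 symbols changed. Only probes with 1 symbol were used for genes, which gave 18354 genes, of which 5600 had more than 1 probe. A gene was represented by its probe with the highest mean over all arrays. Genes were kept when this mean was above the median of the means of all probes, 7.46, which left 10862 genes. No genome build is named with the values, so no coordinates are given.

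Differences were tested with lmFit and eBayes (trend) of limma 3.58.1 in R 4.3.3, with 1 mean per group over all 9 arrays, so that the groups shared an estimate of the spread. The residual degrees of freedom were 6 and the prior added 13.3. All tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes of a comparison, and genes with adjusted p under 0.05 were called. The median SD within groups was 0.0669 on the log2 scale. Input tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

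Before the data were examined, 32 gene lists of pathways and cell type markers were fixed, together with the tests, the alternatives and the rule for naming genes. Lists with at least 5 tested members were compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over the 31 lists tested. The estimated correlation, fry and a rank version were alternatives. The rule named the 5 largest rises and 5 largest falls of the deprivation and coculture comparisons and the 3 largest rises and 3 largest falls of the comparison that differs in both, among called genes whose groups did not overlap. It also named up to 3 called members, by smallest p, of each list that camera called in the deprivation and coculture comparisons, for at most 8 lists each, the 5 genes with the largest fall and the 5 with the largest rise that coculture called in the opposite direction, the 3 brightest fibroblast markers, and GLUL, ASNS, DDIT3, MYC and TXNIP among those named whatever their values. It gave 52 names, not all of which are reported. Every other gene named was chosen after its values were seen, and so were 2 further lists, small nucleolar RNA host genes and clustered histone genes. FTH1 had no probe with a name here and was not analysed here.

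The share of deprivation-called genes that coculture called in the opposite direction was counted, with Wilson 95% intervals that treat genes as independent. Since both comparisons use the deprived monoculture arrays, the correlation and covariance of the differences were also computed in 100 draws with the genes' own spread and no group difference, and after seeing the data the deprived arrays were divided so that the comparisons shared none. The percentage by which a list shifted toward complete medium is the mean deprived minus coculture level over the mean deprived minus complete level. It was computed per coculture array, for members that deprivation changed at least 1.5-fold, and its SD covers the spread of the 3 coculture arrays only. Probes of closely related sequences, such as FTH1P3 with ferritin heavy chain, PTTG3P with PTTG1, and HSPA1A with HSPA1B, may pick up each other's RNA, so these genes are uncertain.

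The tests were checked on simulated data with the levels of complete medium, the fitted spreads and 200 changed genes among 10862. For deprivation, 70.6% of genes set to differ by 0.25 on the log2 scale were called, and 100% of those set to differ by 0.5 and by 1, with 9 false calls among 10662 unchanged genes. For coculture against monoculture the shares were 75% and 100%, with 6 false calls, and for the comparison that differs in both they were 66.2% and 100%, with 18 false calls. In a simulated list test, the 1 list that was shifted was found and 0 of the 30 other lists were called. Genes were drawn independently there, so it cannot show false list calls that come from genes changing together. Alternatives were no filter on dim probes or a filter at the 75th percentile, variance moderation without trend or robust, other uses of several probes, renewed quantile normalization, centring on medians, only the groups compared, array weights, the replicate number as a block, stricter thresholds, and leaving out each array in turn.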

Results

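Gene expression was measured in HeyA8 ovarian cancer cells kept for 24 h in complete medium, in medium without glutamine, or in medium without glutamine together with cancer-associated fibroblasts on inserts. Each condition had 3 arrays, and 10862 genes were tested. Arrays of a group correlated at r between 0.996 and 0.998 across probes. The correlations were lowest between the monocultures, from 0.960 to 0.963. Coculture arrays correlated at 0.989 to 0.990 with deprived monoculture and at 0.979 to 0.981 with complete medium. Levels are on the deposited log2-like scale, whose floor lay near 7.4, and are given as mean ± SD with n = 3; differences carry the SE of the fit.

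The comparison of monocultures asked what 24 h without glutamine changed in the cancer cells. Genes of cell division fell steeply and together, while genes of the amino acid stress response and several inflammatory cytokines rose. UBE2C, a ubiquitin-conjugating enzyme of the anaphase-promoting complex, was 18.2-fold lower without glutamine, at 8.14 ± 0.04 (SD, n = 3) against 12.33 ± 0.02. DDIT3, which encodes the stress transcription factor CHOP, was 8.06-fold higher, at 10.78 ± 0.03 against 7.77 ± 0.12. ASNS, the enzyme that makes asparagine from aspartate with glutamine as nitrogen donor, was 4.56-fold higher, at 12.09 ± 0.12 against 9.90 ± 0.12. Of the genes tested, 5898 (54.3%) were called, 3254 higher and 2644 lower, relative to the common distribution of the arrays. At least 2-fold differences were found for 462 of them, 169 higher and 293 lower.

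All 40 tested genes of the mitosis list fell (40 also adjusted over the list alone), with a median log2 difference of -2.6. Its camera adjusted p was 1.29e-41, and 0.0024 with an estimated correlation. Besides UBE2C they included CDC20, an activator of the anaphase-promoting complex (log2 difference -4.11, SE 0.072), and CDK1, the kinase that drives entry into mitosis (-3.76, SE 0.066). Of the DNA replication list, 36 of 38 genes fell and 0 rose (37 and 0 adjusted over the list alone; camera adjusted p = 1.53e-25). GINS2, a subunit of the replicative helicase, was 4.69-fold lower, and FEN1, the flap endonuclease that processes Okazaki fragments, was 4.12-fold lower. TOP2A, the DNA topoisomerase of dividing cells and a member of the mitosis list, was 12.4-fold lower. Large falls outside the lists were those of the replication-associated PCLAF (10.4-fold lower) and of CDKN3 (11.1-fold lower). PTTG3P, a pseudogene whose probe may also pick up PTTG1, was 12.1-fold lower. Purine and pyrimidine synthesis genes fell for 17 of 22 members, with 0 higher (18 and 0 adjusted over the list alone; camera adjusted p = 2.09e-06). Its members TK1, RRM1 and TYMS, which supply deoxynucleotides, stand in the replication list too. They were 4.84-fold, 4.80-fold and 4.63-fold lower.

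Of 32 tested genes of the amino acid response, targets of the transcription factor ATF4, 29 rose and 0 fell (29 and 0 adjusted over the list alone; camera adjusted p = 5.67e-15). Next to DDIT3 and ASNS, TRIB3, a pseudokinase induced by stress, was 7.53-fold higher, and PPP1R15A, a regulatory subunit of the phosphatase that acts on eIF2-alpha, 5.74-fold higher. PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, was 4.59-fold higher. The cytosolic aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, rose for 12 of 17 members and fell for 2 (13 and 2 adjusted over the list alone; camera adjusted p = 0.000562), with WARS1 3.98-fold higher. Amino acid transporters rose for 13 of 23 and fell for 3 (13 and 3 adjusted over the list alone; camera adjusted p = 0.0057). The glutamine transporter SLC1A5 was 2.71-fold higher, and the partners SLC7A5 and SLC3A2, which exchange glutamine for large neutral amino acids, were 3.44-fold and 3.33-fold higher. These partners and SLC7A1, SLC7A11, SLC6A9 and SLC38A2, which also rose, stand in the amino acid response list too. The calls of these lists are therefore not independent. Genes of glutamine and glutamate metabolism went both ways, 10 higher and 8 lower of 21 (10 and 8 adjusted over the list alone), and the list was not called (camera adjusted p = 0.124). Glutamine synthetase, GLUL, lay close to the floor in every group, at 7.46 ± 0.09 in complete medium, 7.49 ± 0.03 in deprived monoculture and 7.45 ± 0.08 in coculture, where a difference is hard to detect (adjusted p = 0.688 for deprivation).

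Inflammatory genes under NF-kB control rose for 16 of 21 members and fell for 1 (16 and 1 adjusted over the list alone; camera adjusted p = 5.17e-08). IL6 was 5.73-fold higher, from 7.48 ± 0.01 near the floor, SOD2, the mitochondrial superoxide dismutase, was 5.30-fold higher and the chemokine CXCL2 4.76-fold higher. CXCL8, the chemokine interleukin-8, was 5.28-fold higher. Targets of p53 rose for 15 of 23 and fell for 3 (15 and 3 adjusted over the list alone; camera adjusted p = 4.28e-05). Among them GDF15, a stress-induced cytokine that is also in the amino acid response list, was 6.38-fold higher, TP53INP1 3.01-fold and the growth arrest gene GADD45A 2.68-fold higher. Lysosome and autophagy genes rose for 23 of 35 and fell for 3 (26 and 3 adjusted over the list alone; camera adjusted p = 4.28e-05). The autophagy receptor SQSTM1 was 3.62-fold higher, and the autophagosome proteins MAP1LC3B and GABARAPL2 3.34-fold and 1.77-fold. NRF2 targets, which serve the defence against oxidants, rose for 10 of 20 and fell for 3 (10 and 4 adjusted over the list alone; camera adjusted p = 0.00589). Immediate early genes rose for 14 of 25 and fell for 3 (14 and 3 adjusted over the list alone; camera adjusted p = 0.00141, and adjusted p = 0.0636 with an estimated correlation). MYC, a member, was 1.83-fold higher. Interferon-stimulated genes rose for 11 of 25 and fell for 2 (11 and 2 adjusted over the list alone; camera adjusted p = 0.0218, and adjusted p = 0.117 with an estimated correlation).

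Genes of lipid and energy metabolism were lower. Cholesterol synthesis genes fell for 11 of 17 members and rose for 2 (12 and 2 adjusted over the list alone; camera adjusted p = 6.25e-05). INSIG1, a sterol-responsive regulator, was 4.92-fold lower, ACAT2 3.66-fold and HMGCS1, an early enzyme of the pathway, 2.37-fold lower. Fatty acid synthesis genes fell for 9 of 16 and rose for 2 (10 and 2 adjusted over the list alone; camera adjusted p = 0.00124), and SCD, the stearoyl-CoA desaturase, was 6.47-fold lower. Glycolysis genes fell for 14 of 22 and rose for 3 (15 and 3 adjusted over the list alone; camera adjusted p = 0.00267, and adjusted p = 0.0622 with an estimated correlation). Tricarboxylic acid cycle genes fell for 12 of 22 and rose for 3 (12 and 3 adjusted over the list alone; camera adjusted p = 0.00537). Oxidative phosphorylation genes fell for 22 of 40 and rose for 4 (23 and 4 adjusted over the list alone; camera adjusted p = 0.00495, and adjusted p = 0.165 with an estimated correlation). Of 8 tested epithelial markers 7 fell and 0 rose (7 and 0 adjusted over the list alone; camera adjusted p = 0.000532, and adjusted p = 0.0636 with an estimated correlation), with the keratin KRT8 2.74-fold lower.

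The largest single rise was that of ALOX5AP, the 5-lipoxygenase-activating protein of leukotriene synthesis, from 8.84 ± 0.02 to 13.05 ± 0.04 (18.6-fold; adjusted p = 2.15e-20). FTH1P3, a ferritin pseudogene whose probe may pick up ferritin heavy chain RNA, was 9.61-fold higher, and TXNIP, a thioredoxin-binding protein that limits glucose uptake, 8.71-fold higher. Other members of the TXNIP list were not called, and with 4 tested members the list was not tested. The 12 remaining lists were not called by camera. The adjusted p was 0.794 for serine and one-carbon metabolism, 0.982 for endoplasmic reticulum chaperones, 0.718 for targets of TGF-beta and YAP, and 0.615 for extracellular matrix and mesenchymal genes. For fibroblast, leukocyte and endothelial markers it was 0.0627, 0.843 and 0.843, for hypoxia-inducible factor targets 0.111, for cytosolic ribosomal proteins 0.718, for ribosome biogenesis 0.0938, for heat shock proteins 0.924 and for metallothioneins 0.237. Altogether camera called 18 of 31 lists, 9 higher and 9 lower, and 13 of these calls held with an estimated correlation. The adjusted p of these 13 was then larger, from 0.000484 for DNA replication to 0.046 for NRF2 targets and for amino acid transporters. It was 0.0434 for p53 targets. With a fold of at least 1.5 as a further condition, 1399 genes were called.

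**Figure D1:**
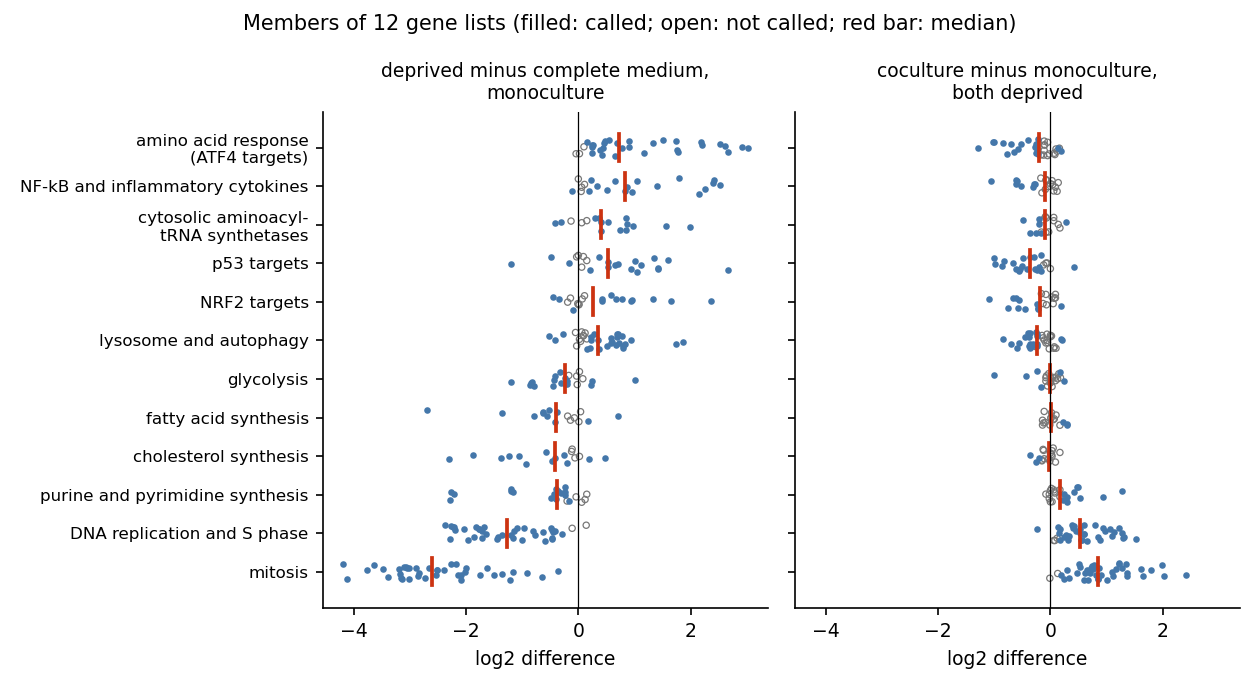
Log2 differences of the members of 12 gene lists for deprived minus complete medium in monoculture (left) and for coculture minus monoculture without glutamine (right). Each point is a gene, filled if called, the red bar is the median of the list; the mitosis list has a median of -2.6 on the left and 0.84 on the right, while the cholesterol list has medians of -0.42 and -0.03.

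Coculture with fibroblasts was compared with monoculture, both without glutamine, to ask what the fibroblasts changed in deprived cancer cells. Genes of the mitosis and DNA replication lists were higher in coculture, and targets of p53 were lower. UBE2C was 5.37-fold higher in coculture, at 10.57 ± 0.05 (SD, n = 3) against 8.14 ± 0.04, CDC20 was 4.08-fold and CDK1 3.97-fold higher. TXNIP was 3.69-fold lower, at 10.33 ± 0.10 against 12.22 ± 0.03, and DDIT3 2.43-fold lower. ASNS differed little, at 11.97 ± 0.03 against 12.09 ± 0.12 (log2 difference -0.12, SE 0.073; adjusted p = 0.251). Of 10862 genes, 3022 (27.8%) were called, 1380 higher and 1642 lower. At a fold of at least 1.5 there were 281, of which 191 were higher and 90 lower, and at least 2-fold differences were found for 65, 54 higher and 11 lower.

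The mitosis list was higher for 38 of 40 members and lower for 0 (39 and 0 adjusted over the list alone), with a median log2 difference of 0.84. Its camera adjusted p was 1.42e-48, and 0.0018 with an estimated correlation. DNA replication genes were higher for 33 of 38 and lower for 1 (34 and 1 adjusted over the list alone; camera adjusted p = 6.32e-29). PRIM1, the catalytic subunit of DNA primase, was 2.48-fold higher, CDC45, part of the replicative helicase, 2.33-fold and FEN1 2.21-fold higher. The 1 lower member was PCNA, the sliding clamp, with a log2 difference of -0.24. Purine and pyrimidine synthesis genes were higher for 10 of 22 and lower for 0 (10 and 0 adjusted over the list alone; camera adjusted p = 2.07e-05), led by RRM1 (2.42-fold), TK1 (1.90-fold) and TYMS (1.43-fold). TOP2A and PCLAF were 3.45-fold and 3.83-fold higher.

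Targets of p53 were lower for 18 of 23 members and higher for 1 (18 and 1 adjusted over the list alone; camera adjusted p = 5.22e-11). GDF15 was 2-fold lower, GADD45A 1.97-fold and TRIAP1, an inhibitor of apoptosis, 1.78-fold lower. Amino acid response genes were lower for 16 of 32 and higher for 2 (18 and 2 adjusted over the list alone; camera adjusted p = 1.48e-06). PPP1R15A was 2.03-fold and the transcription factor ATF3 1.8-fold lower. The 2 higher members were PSAT1, an enzyme of serine synthesis, with a log2 difference of 0.19, and NUPR1 with 0.13. The call of PSAT1 was lost without deprived monoculture array 1 (adjusted p = 0.0614), without coculture array 1 (0.078) and without coculture array 3 (0.0597). With the mean of its probes PSAT1 differed by 0.08 (adjusted p = 0.265), and over all alternatives its adjusted p ranged from 0.00393 to 0.265. Lysosome and autophagy genes were lower for 18 of 35 and higher for 2 (20 and 2 adjusted over the list alone; camera adjusted p = 1.31e-05). Among them the proton pump subunit ATP6V1B2 was 1.62-fold, MAP1LC3B 1.8-fold and SQSTM1 1.5-fold lower. NRF2 targets were lower for 10 of 20 and higher for 1 (11 and 1 adjusted over the list alone; camera adjusted p = 0.000155), with the thioredoxin reductase TXNRD1 2.12-fold, NQO1 1.70-fold and SRXN1 1.54-fold lower. NF-kB genes were lower for 8 of 21 and higher for 0 (8 and 0 adjusted over the list alone; camera adjusted p = 0.00283). IL6 was 2.07-fold lower, while CXCL2 had a log2 difference of -0.04 (adjusted p = 0.703).

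Immediate early genes were lower for 12 of 25 and higher for 0 (12 and 1 adjusted over the list alone; camera adjusted p = 0.000227, and adjusted p = 0.0608 with an estimated correlation). The phosphatase DUSP5 was 1.87-fold lower, the transcription factor KLF4 1.8-fold, IER5 1.51-fold and MYC 1.36-fold lower. Heat shock proteins were lower for 9 of 21 and higher for 2 (9 and 2 adjusted over the list alone; camera adjusted p = 0.0283, and adjusted p = 0.0945 with an estimated correlation). Metallothioneins were lower for 3 of 6 and higher for 0 (3 and 0 adjusted over the list alone; camera adjusted p = 0.0371, and adjusted p = 0.13 with an estimated correlation). Epithelial markers were higher for 3 of 8 and lower for 0 (3 and 0 adjusted over the list alone; camera adjusted p = 0.00832, and adjusted p = 0.169 with an estimated correlation). Serine and one-carbon genes were higher for 3 of 15 and lower for 0 (3 and 0 adjusted over the list alone; camera adjusted p = 0.0283, and adjusted p = 0.0945 with an estimated correlation). Without deprived monoculture array 1 the camera adjusted p was 0.0504 for both the metallothionein and the serine list, and without coculture array 1 it was 0.0598 for the metallothioneins. Testing without the filter on dim probes and testing on ranks also ended the metallothionein call (0.0566 and 0.191), and ranks ended that of the heat shock proteins (0.0543). Further falls in coculture were those of FTH1P3 (3.05-fold) and the transcriptional regulator TSC22D1 (2.26-fold).

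The cholesterol list was not called in coculture (camera adjusted p = 0.257), with 0 of 17 members higher and 3 lower (0 and 3 adjusted over the list alone). INSIG1 stood at 8.38 ± 0.06 against 8.41 ± 0.10 and ACAT2 at 8.92 ± 0.15 against 8.89 ± 0.14, so their differences were smaller than the spread between arrays. Fatty acid synthesis (adjusted p = 0.427), glycolysis (0.81), the tricarboxylic acid cycle (0.908) and oxidative phosphorylation (0.15) were not called either. The same held for aminoacyl-tRNA synthetases (0.2), amino acid transporters (0.211) and glutamine and glutamate metabolism (0.427). Also not called were targets of TGF-beta and YAP (0.507), extracellular matrix and mesenchymal genes (0.15), interferon-stimulated genes (0.766) and hypoxia-inducible factor targets (0.198). The adjusted p was 0.787 for endoplasmic reticulum chaperones, 0.348 for ribosomal proteins and 0.196 for ribosome biogenesis. It was 0.908 for leukocyte and 0.81 for endothelial markers. In all, 13 of 31 lists were called, 5 higher and 8 lower, and 8 held with an estimated correlation. The adjusted p of these 8 was then larger, from 0.000334 for DNA replication to 0.0407 for NF-kB genes. It was 0.0139 for p53 targets.

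Fibroblast markers were followed because the cancer cells had shared their medium with fibroblasts. Most lay at the floor in coculture as in monoculture: COL1A2 stood at 7.46 ± 0.11 in coculture and 7.45 ± 0.03 in deprived monoculture, COL3A1 at 7.39 ± 0.02 and 7.39 ± 0.08, and DCN at 7.41 ± 0.07 and 7.42 ± 0.02. COL1A1 stood at 7.56 ± 0.13 and 7.48 ± 0.07. Of 16 tested markers 5 were higher in coculture and 1 lower (5 and 1 adjusted over the list alone), and the list was not called (camera adjusted p = 0.102). The brightest were ACTA2, smooth muscle actin, IGFBP4 and the secreted Wnt antagonist SFRP1, which the cancer cells also expressed in monoculture. ACTA2 was 1.52-fold lower in coculture, SFRP1 1.28-fold and IGFBP4 1.18-fold higher. The IGFBP4 call was lost without deprived monoculture array 3 (adjusted p = 0.0534) and without coculture array 3 (0.0862), and over all alternatives its adjusted p ranged from 0.00673 to 0.0862. The other markers called higher, named after their values were seen, were FBLN1, from 7.54 ± 0.11 in deprived monoculture to 7.93 ± 0.03 in coculture, FAP, from 7.41 ± 0.05 to 7.65 ± 0.02, and COL5A2, from 7.84 ± 0.07 to 8.01 ± 0.03. In complete medium they stood at 8.35 ± 0.06, 7.82 ± 0.13 and 8.47 ± 0.03.

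**Figure D2:**
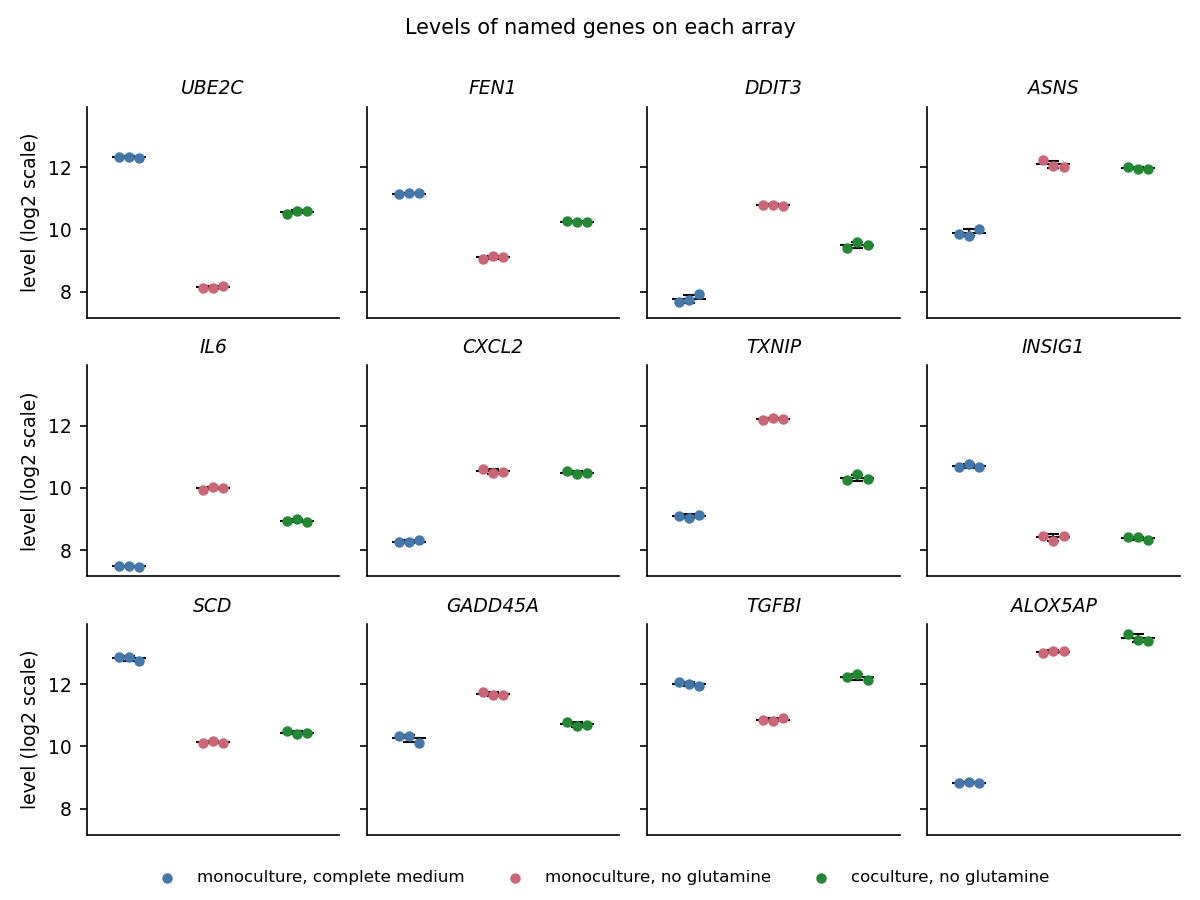
Levels of 12 genes on the deposited log2-like scale, with a point per array, bars for the mean and whiskers for the SD of the 3 arrays of a group. UBE2C in coculture (10.57) lies between complete medium (12.33) and deprived monoculture (8.14), whereas INSIG1 in coculture (8.38) lies beside deprived monoculture (8.41).

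The comparisons were then set against each other, gene by gene, to ask how far the levels in coculture lay back toward those in complete medium. Of the 5898 genes called for deprivation, 2429 (41.2%, Wilson 95% interval 39.93 to 42.44) were called in the opposite direction in coculture and 121 (2.05%) in the same direction. Among the 1399 that deprivation changed at least 1.5-fold, 1064 (76.1%) were called in the opposite direction and 18 in the same. These larger changes lay back by a median of 36.7% of the deprivation difference, and 96.2% of them were still called against complete medium in the direction of deprivation. Coculture levels of 33.5% of all deprivation-called genes, and of 25.7% of the larger ones, lay nearer to complete medium than to deprived monoculture. The restriction to larger changes was chosen after seeing the data.

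Genes raised by deprivation and lower in coculture numbered 1368, against 491.9 for independent lists, and those lowered by deprivation and higher in coculture 1061, against 335.9. The differences of the comparisons had r = -0.786 across genes, which are not independent replicates, against -0.501 on average in draws without any group difference. Their covariance was -0.0816 against -0.00181. The signs were opposite for 74.3% of genes against 66.7% in the draws. In the draws no group differs, so they cannot say how much of the observed opposition comes from the shared arrays. The deprived arrays were then divided in all 6 ways that leave none shared, a choice made after seeing the data, with a lone array assumed to vary like the other groups. The correlation was then -0.748 to -0.705 and the signs were opposite for 66.1% to 69.4% of genes. Unrelated differences would then show no correlation and about as many equal as opposite signs, if the deprived arrays had no error in common. Most of the opposition thus remained when no single array was shared. Both comparisons still used the deprived group, so an error common to all its arrays would oppose them here too. The division cannot remove such an error. Between 1359 and 2002 genes were called in opposite directions, against 411.5 to 621.7 for independent lists, or 24.8% to 43% of the deprivation-called genes.

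The percentage by which each gene list lay back was computed on the log2 scale. NRF2 targets raised by deprivation shifted toward complete medium by 53.5% ± 2.11 (SD, n = 3 coculture arrays; 8 genes) and p53 targets by 52.6% ± 1.98 (11 genes). Replication genes shifted by 47.9% ± 0.514 (29 genes) and mitosis genes by 38.0% ± 1.28 (39 genes). Immediate early genes and the lysosome list shifted by 45.9% ± 4.36 and 45.1% ± 2.22. Amino acid response genes shifted by 28.7% ± 0.514 (18 genes), NF-kB genes by 20.9% ± 1.69 (12 genes) and aminoacyl-tRNA synthetases by 17.9% ± 3.14 (7 genes). Glycolysis genes shifted by 11.9% ± 3.93 and fatty acid synthesis genes by 8.04% ± 3.05 (5 genes each), and cholesterol genes lay at -3.97% ± 1.98 (6 genes). For comparison, all genes raised at least 1.5-fold shifted by 35.5% ± 0.591 and all genes lowered by 38.0% ± 1.09. Within the amino acid response the members were unequal: TRIB3 shifted by 26.3%, DDIT3 by 42.5% and ATF3 by 73.0%, while ASNS and PCK2 shifted by 5.45% and 4.90%. The order of the lists depends on the scale. As medians over genes on the linear scale, mitosis genes shifted by 19.1% ± 1.49 and replication genes by 34.1% ± 2.09, and NF-kB genes (26.8% ± 4.68) and amino acid response genes (43.4% ± 2.16) then lay above the mitosis genes, not below them. All genes raised at least 1.5-fold shifted by 44.8% ± 1.6 there and all genes lowered by 26.7% ± 0.755, while cholesterol genes lay at -3.17% ± 1.39.

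**Figure D3:**
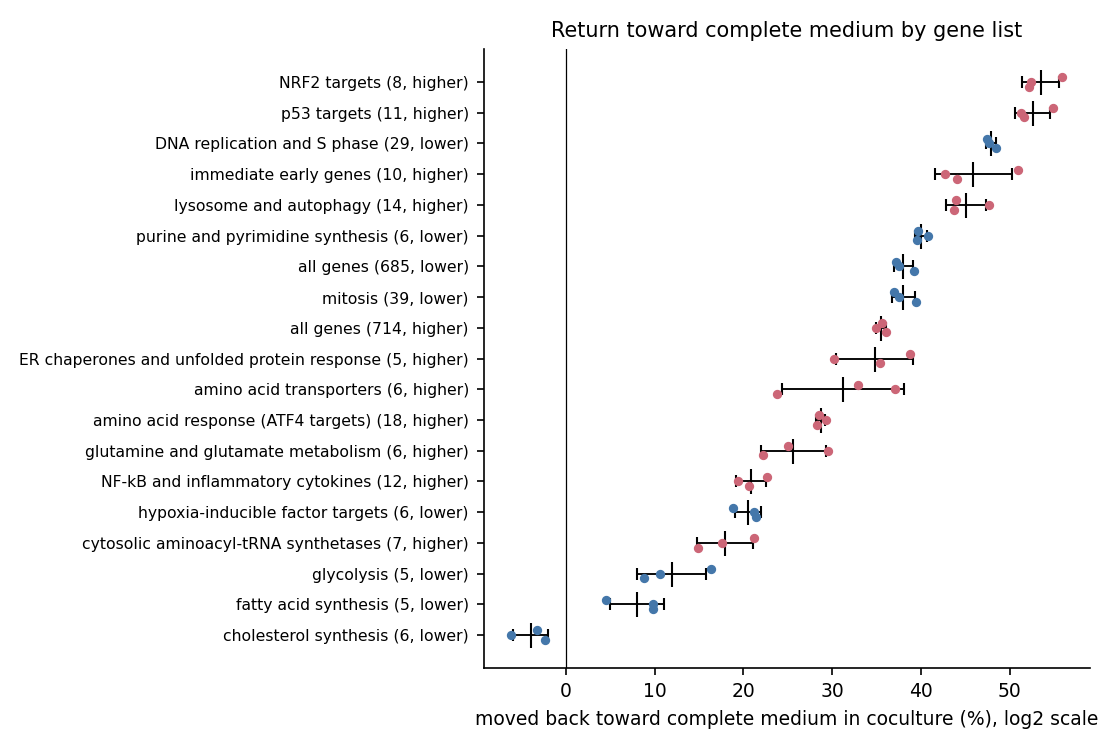
Percentage by which members of each list that deprivation changed at least 1.5-fold lay back toward complete medium in coculture, on the log2 scale, with a point per coculture array, the mean and the SD (n = 3). Labels give the number of genes and their direction under deprivation (red higher, blue lower); the lists run from cholesterol synthesis at -3.97% to NRF2 targets at 53.5%.

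**Figure D4:**
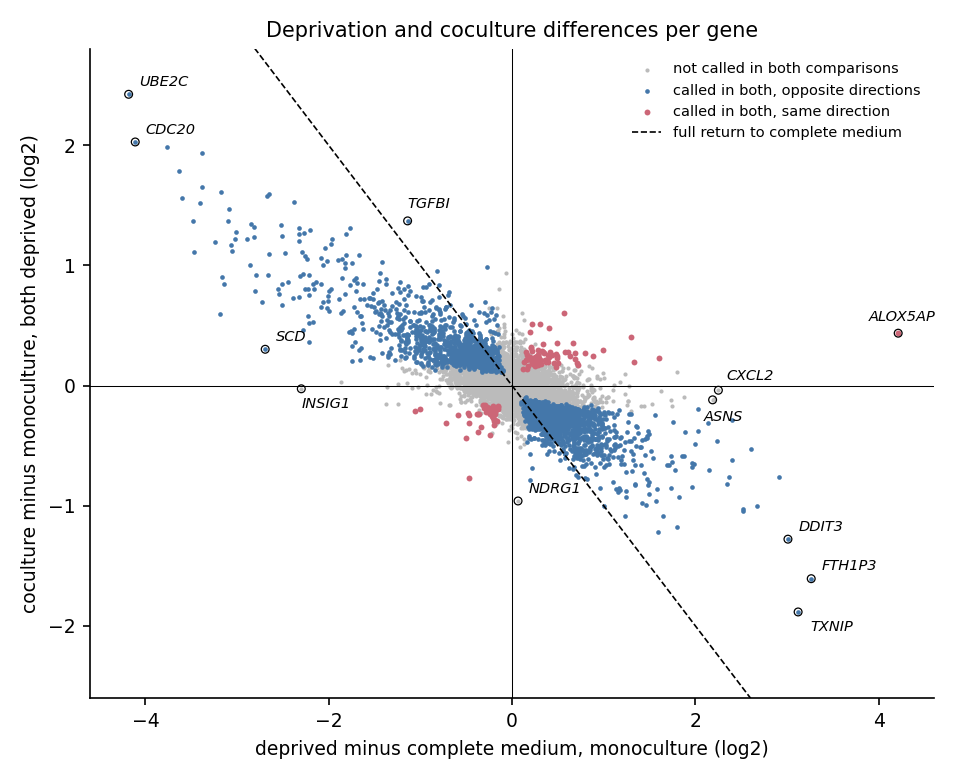
Log2 difference of each of 10862 genes for deprived minus complete medium in monoculture (x axis) and for coculture minus monoculture without glutamine (y axis). Genes called in both comparisons are blue when the directions oppose (2429) and red when they are the same (121), and the dashed line marks levels in coculture equal to those in complete medium.

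Coculture without glutamine was last compared with monoculture in complete medium, conditions that differ in both medium and culture. Division genes were still lower and the amino acid response still higher than in complete medium. KIF20A, a mitotic kinesin, was 6.02-fold lower, at 8.10 ± 0.01 (SD, n = 3) against 10.69 ± 0.06, SCD 5.25-fold and CDKN3 5.13-fold lower. ALOX5AP was 25.1-fold higher, at 13.49 ± 0.12 against 8.84 ± 0.02, CXCL2 4.63-fold and TRIB3 4.43-fold higher. Of 10862 genes 4670 (43.0%) were called, 2425 higher and 2245 lower, with more higher than lower. Among the 696 that differed at least 1.5-fold the balance was the other way, 312 higher and 384 lower, as among the 204 that differed at least 2-fold, 77 higher and 127 lower.

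All 40 mitosis genes were lower (40 also adjusted over the list alone; camera adjusted p = 6.11e-46), with a median log2 difference of -1.66, and 36 of 38 replication genes were lower and 2 higher (36 and 2 adjusted over the list alone; camera adjusted p = 2.37e-21). Of the amino acid response 29 of 32 were higher and 0 lower (30 and 0 adjusted over the list alone; camera adjusted p = 1.48e-18), and of the NF-kB genes 14 of 21 were higher and 0 lower (14 and 0 adjusted over the list alone; camera adjusted p = 6.37e-09). Cholesterol synthesis genes were lower for 13 of 17 and higher for 1 (13 and 1 adjusted over the list alone; camera adjusted p = 1.23e-07). Camera called 19 of 31 lists, 9 higher and 10 lower. With an estimated correlation 12 held, with larger adjusted p, from 0.000824 for DNA replication to 0.0382 for the lysosome list. The p53 target list, higher for 12 of 23 and lower for 5 (12 and 5 adjusted over the list alone; camera adjusted p = 0.0156), was among those that did not (adjusted p = 0.152 with an estimated correlation). Hypoxia-inducible factor targets were lower for 13 of 25 and higher for 2 (13 and 2 adjusted over the list alone; camera adjusted p = 0.002, and adjusted p = 0.173 with an estimated correlation).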

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

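Of the tests in this part, only the splits of the arrays were chosen before the results were seen; those of the shared and the divided arrays, of mixing, of matched random lists and of fibroblast RNA were chosen after. Probes with no gene name are outside the comparisons of genes. Of 3117 such probes tested, 966 differed with deprivation, 362 between coculture and monoculture, and 723 between coculture without glutamine and complete medium, at adjusted p under 0.05. In each comparison, 1 of the 10 splits of the 6 arrays, the real one, gave as many genes as the real one, and 10 splits are too few for a share under 0.05. The real counts were 5898, 3022 and 4670 genes and the highest other count by limma was 0 in each comparison. At an unadjusted p under 0.05 the other splits reached 350, 544 and 329 genes. Each other split mixed arrays of both groups, so the real differences widened its spread and kept its count low. These counts therefore do not show what chance would give.

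Coculture differences opposed deprivation differences across genes. The deprived monoculture arrays, which both comparisons share, make such values oppose by construction. The covariance of -0.0816 lay far outside the draws without a group difference (-0.00192 to -0.00168). It was -0.0806 to -0.0768 with the deprived arrays divided so that none was shared. The spread of single shared arrays is thus not the whole cause. An error common to all deprived arrays would enter both comparisons even then, so it cannot be excluded. A mixture of RNA from fully fed and fully deprived cells in 1 proportion would move all gene groups alike on the linear scale. The cholesterol genes lay at -3.17% ± 1.39 (SD, n = 3) there and all lowered genes at 26.7% ± 0.755. The cholesterol list was the lowest of the lists and was picked after its value was seen. All genes raised at least 1.5-fold lay at 44.8% ± 1.6. If the scale is log2, these unequal values argue against that mixture as the only cause. A mixture together with other effects of coculture was not tested. A partial easing of deprivation by the fibroblasts is a hypothesis that may account for the pattern; effects of coculture that do not depend on glutamine stay open, as coculture in complete medium was not analysed here.

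Some gene groups lay back by other percentages than matched genes. On the log2 scale, 10000 random lists were matched on the size of the deprivation change and on the deprived level. Cholesterol synthesis was at percentile 0 (-3.97%, central 95% of the random lists 31% to 56.4%), fatty acid synthesis at 0.08 (8.04%, 21.5% to 58.2%) and replication at 100 (47.9%, 31.3% to 43%), all outside the central 99%. The random lists drew each gene independently, so lists of genes that change together may vary more than these percentiles allow. For the 2 lipid lists the distance was wide, which argues against size and place on the scale as the whole account. For replication it was small, and the median gene lay back by 41.6%, so no conclusion is drawn. The percentiles of the NF-kB list (1.84), the p53 targets (99) and the NRF2 targets (98.89) lay outside the central 95% but inside the central 99%. For them size and place on the scale cannot be told apart from a difference between gene groups. Of the 17 lists, 10 lay inside the central 95%, among them the amino acid response (11.16), mitosis (18.61), transporters (26.25), lysosome (95.09) and immediate early genes (96.22), and 7 outside, which also include aminoacyl-tRNA synthetases (2.19). Why the cholesterol genes stayed near their deprived levels was not tested.

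TGFBI, an extracellular matrix protein, was 2.59-fold higher in coculture than in deprived monoculture, at 12.23 ± 0.09 against 10.86 ± 0.04. Deprivation had lowered it 2.2-fold (log2 difference -1.14, adjusted p = 6.17e-12), so most of its rise in coculture regained the level of complete medium. It also lay above complete medium (log2 difference 0.23, adjusted p = 0.00578, and 0.00123 to 0.045 over the alternatives). LTBP2, TAGLN and COL4A1, singled out like TGFBI after their values were seen, differed by 0.58, 0.51 and 0.69, while in the list of TGF-beta and YAP targets, which holds TGFBI, LTBP2 and TAGLN, 6 of 21 were higher and 4 lower (ACTA2 -0.6, TGIF1 -0.6, CCN1 -0.31 and AXL -0.3) and the list was not called (camera adjusted p = 0.507). RNA from fibroblasts, which the inserts keep apart from the cancer cells, could raise such genes, but the 18 fibroblast markers at the floor in both monocultures had a median difference of -0.004 (-0.064 to 0.038). The abundant fibroblast genes COL1A1, COL1A2, COL3A1 and DCN had coculture levels of 7.56, 7.46, 7.39 and 7.41, which argues against it, although FBLN1, FAP and COL5A2, which the cancer cells expressed in complete medium, rose by 0.39, 0.24 and 0.17; how brightly their probes respond to fibroblast RNA was not tested. A response of the cancer cells to the fibroblasts stays open as a hypothesis.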

How the results depend on the processing

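All alternatives were chosen before the results were seen, except the count among deprivation genes with at least a 1.5-fold change and the division of the deprived arrays. Requiring 1.5-fold gave 1399 genes for deprivation, 281 for coculture against monoculture and 696 for both differences, as fewer genes pass by construction; 68% of the 281 were higher, against 45.7% of all called. With every probe tested by itself, 2806 were higher and 2946 lower for both differences, against 2425 and 2245 genes. At adjusted p under 0.01 coculture called 1963 genes. The other settings kept each count within 1.5 times the reported one, and leaving out each array in turn gave 5447 to 5876, 2464 to 3000 and 4153 to 4799 genes.

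The share of deprivation genes that coculture called in the opposite direction, 41.2%, was 33.4% at adjusted p under 0.01, 18.7% with 1.5-fold required in both comparisons and 76.1% with it required of deprivation alone. It was 38% without a filter, 48.8% with the filter at the 75th percentile, 42.8% without trend, 43.2% with array weights, and 34.9% to 43% when leaving out each array; the cause was not tested. With deprived arrays 1, 2 or 3 alone for deprivation and the others for coculture, so that none was shared, it was 37.9%, 39.2% and 43%, and with them alone for coculture 29.4%, 24.8% and 25.3%, with fewer arrays in each comparison. Lists called by fry, which does not compare a list with other genes, numbered 28, 24 and 30. With an estimated correlation 8 were called for coculture and 12 for both differences. By fry the cholesterol list was lower in coculture (adjusted p = 0.000227; 0.000227 to 0.336 over the alternatives).

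Replicate numbers did not pair the arrays: only 4 of 9 arrays correlated best with their own number. With the number as a block 5802, 2901 and 4563 genes were called and the share was 40.7%. The NRF2 list lost its call for both differences there (adjusted p = 0.052), and without complete arrays 1 or 3 or coculture array 1 (0.059, 0.0511 and 0.0512), on ranks (0.0868) and with an estimated correlation (adjusted p = 0.118; 4.12e-06 to 0.118 over the alternatives). The oxidative phosphorylation list lost it without complete array 3 (0.0752) or coculture array 1 (0.0558) and with an estimated correlation (adjusted p = 0.239; 0.00188 to 0.239 over the alternatives).

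When an array was left out, 2138 results of named genes stayed on their side of the threshold, called or not, 9 lost a call and 4 gained one; under the other settings these counts were 2830, 37 and 7. For lists, called or not, they were 827, 8 and 2, and 502, 22 and 34, the gains mostly by fry. 0 named genes or lists reversed. The pseudocounts planned for linear values were not run, as the values are logarithmic. Signal near the floor limits what dim genes can show.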

Other observations

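Of the tests in this part, those of the small nucleolar RNA host genes and of the clustered histone genes were chosen after the results were seen, as were the genes named. The camera p-values here were adjusted over these 2 lists only, not over the fixed lists. Since the same data led to the lists, these p-values describe them and are no independent support. Host genes of small nucleolar RNAs, noncoding transcripts that carry these RNAs in their introns, rose with deprivation for 9 of 13 tested members and fell for 0 (camera adjusted p = 0.000148). SNHG5 was 3.35-fold higher (SE 0.065 on the log2 scale, n = 3), EPB41L4A-AS1 3.66-fold and SNHG32 2.34-fold. In coculture 2 were higher and 1 lower (camera adjusted p = 0.735), and SNHG5, EPB41L4A-AS1 and SNHG32 differed by -0.17, -0.1 and 0.1 on the log2 scale. SNHG6 and SNHG8 were higher in coculture, by 0.45 and 0.49, with deprivation differences of -0.15 and -0.09 (adjusted p = 0.0861 and 0.278). Without complete array 2, SNHG6 was called lower with deprivation (-0.22, adjusted p = 0.0169; 0.0169 to 0.327 over the alternatives). Against complete medium 11 of 13 were higher in coculture without glutamine and 0 lower (camera adjusted p = 7.38e-08). Clustered histone genes were lower in coculture for 7 of 20 and higher for 1 (camera adjusted p = 0.024, and adjusted p = 0.118 with an estimated correlation). With deprivation 8 rose and 1 fell (camera adjusted p = 0.0749). The histones went apart: H4C3 was 5.7-fold lower with deprivation, at 11.27 ± 0.68 against 13.78 ± 0.22 (SD, n = 3), while H2AC18 was 2.04-fold and H2BC5 1.76-fold higher.

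Genes that deprivation and coculture called in the same direction numbered 76 higher and 45 lower. The deprived arrays, shared by both comparisons, can lower such counts. The spread of single shared arrays is not the whole reason, as the differences also opposed each other with none shared (r = -0.748 to -0.705). An error common to all deprived arrays would remain there and cannot be excluded. LY96, a partner of Toll-like receptor signalling, was 2.46-fold higher with deprivation and a further 1.32-fold in coculture. The laminin chain LAMA5 was 1.48-fold and a further 1.52-fold higher, and the Wnt antagonist DKK1 1.38-fold and a further 1.7-fold lower. ALOX5AP belonged to them, with 1.35-fold in coculture. Other genes were called in coculture and not for deprivation; whether their 2 differences are unequal was not tested. NDRG1, which is induced by hypoxia and stress, was 1.95-fold lower in coculture, at 9.66 ± 0.09 against 10.62 ± 0.05, and differed by 0.07 with deprivation (adjusted p = 0.575). APCDD1L was 1.91-fold higher, at 10.15 ± 0.29 against 9.21 ± 0.31, and differed by -0.06 with deprivation (adjusted p = 0.746). Unlike these genes, CDH5, known as an endothelial cadherin, was called in both comparisons. It was 4.65-fold lower with deprivation, at 7.55 ± 0.12 against 9.76 ± 0.05, and 1.29-fold higher in coculture, at 7.91 ± 0.06.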
